A study of Mus musculus with 16 samples.

How the data were processed

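RNA was measured in 16 libraries from mouse bone marrow: HSC and Fcgr-negative MPP3 from wild-type and Jak2V617F mice, 4 libraries per group. Per the labels, 7000 to 10000 sorted cells gave at least 10 ng of RNA with an integrity number over 8.0, cDNA was made with a SMARTer Ultra Low kit and 12 to 15 PCR cycles, and libraries were read as 150-base pairs on a NovaSeq X Plus. The strand protocol is not given in the sources used here. The authors list cutadapt 4.0, FastQC, HISAT2 and Salmon with the GRCm38 (mm10) genome; the roles and order of these tools, the versions of the last 3, the transcript set and the Salmon settings are not given in the sources used here. The deposited gene tables hold Salmon's estimated counts (expected counts summed per gene, not normalized), which were the values tested. The authors' Salmon tables also hold TPM (scaled by effective length and library total), which were looked at and not used in any test. Per the file headers they hold effective gene lengths in bases too, used only in 1 alternative. Per the labels the replicate number is also the batch.

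Each table had 31716 rows. The 29806 gene rows were analysed, of which 79 had no symbol and 42 shared one with another row, and the 1910 rows named as single transcripts were left out except in 1 alternative. Symbols and coordinates came from GENCODE release M21. Of the transcript rows, 98 had a gene in that annotation, and 49 could be added to a gene row. Counts were rounded to whole numbers, and 19743 genes had any count. The filter of edgeR (filterByExpr, by group) kept 14179 genes. Library totals had means of 37.3 (control HSC), 39.1 (mutant HSC), 36.9 (control MPP3) and 38.7 (mutant MPP3), each in units of 1e6 counts. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 2.

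Genes were tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3, in 1 model with a coefficient for each of the 4 groups over all 16 libraries, TMM normalization and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called a change. The 5 comparisons were mutant against control in HSC and in MPP3, MPP3 against HSC in control and in mutant mice, and the difference of the mutant effect between MPP3 and HSC. SE was the log2 fold change divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and at least 5 tested members. The 28 lists were written by hand, with 664 genes of which 662 matched a row, and 27 were tested. They covered UPR sensors and regulators, PERK and ATF4 targets, IRE1 and XBP1s targets, ATF6 targets and ER chaperones, cytosolic heat shock, JAK-STAT targets, interferon response, NF-kB targets, HSC identity, granulocyte-monocyte progenitors, neutrophil granules, megakaryocytes and platelets, erythroid cells, lymphoid progenitors, B cells, T and NK cells, mast cells with basophils and eosinophils, dendritic cells with macrophages, stroma and endothelium, mitosis, DNA replication, cell cycle brakes, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation and ribosome biogenesis. The remaining list, of sex-linked genes, served only to check the makeup of the batches. Some genes are on more than 1 list, so the lists are not separate evidence where they share members. Folds against a group with no counts are lower bounds against a floor of 3 counts per library.

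Genes were named by rule. In each comparison these were the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups (overlap was allowed for the difference), leaving out predicted models, pseudogenes and ribosomal or mitochondrial RNA. Further names were up to 4 members of each list with the smallest adjusted p, the kinase gene Jak2, fixed genes of the unfolded protein response and of signalling below the kinase, and sort markers. The tests, lists, rule and most alternatives were chosen before the data were examined. Car1, Gbp4, Spats2, Acsl6 and Gm4951 were named after their values were seen. Some results that the rule covers are not reported here.

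Alternatives were the replicate number as a block, RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, effective-length offsets, mitochondrial, ribosomal RNA and haemoglobin genes left out, a fit on the groups compared alone, camera with an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were transcript rows counted, a block per genotype and batch, and mutant HSC replicates 1 and 4 left out together. Libraries with the same number were compared within batches: over 24 comparisons of deviations from the group mean, r between libraries of the same number ran from -0.03 to 0.16, and 17 matched best with their own number. HSC and MPP3 of 1 genotype did so in 4 of 4 batches in controls (r 0.08 to 0.14) and in mutants (0.08 to 0.16). Groups of different genotype did so in 1 to 3 of 4. The main model did not pair libraries, and only the alternatives with a block used the number. Replicates had r of log2 CPM from 0.933 to 0.971, with no identical pair. The highest r was that of mutant HSC replicates 1 and 4, and the next, of mutant HSC replicates 1 and 2, was 0.958. Why replicates 1 and 4 are so alike was not tested, and the main model treats them as separate samples. Simulated data, in which 200 genes were changed, took the mean and spread of each gene from all 16 libraries, without batches. They do not hold the larger spread among MPP3 libraries, so they do not compare power in MPP3 with that in HSC. The test was also run on these data. It recovered, at 1.5-fold, 2-fold and 4-fold, 19.4%, 52.2% and 78.8% of them in the HSC design, 17.9%, 53.7% and 84.8% in the MPP3 design, 25.4%, 61.2% and 87.9% for MPP3 against HSC in controls, 16.4%, 47.8% and 87.9% in mutants, and 0%, 25.4% and 69.7% for the difference, with 4, 2, 7, 2 and 1 false calls among 104, 106, 123, 103 and 64. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and label files were read with jsonlite 2.0.0.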

Results

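RNA sequencing measured transcript abundance in 2 cell types sorted from mouse bone marrow. HSC are haematopoietic stem cells. MPP3 are multipotent progenitors with a myeloid bias, here the fraction without Fcgr, the receptor family that marks granulocyte-monocyte progenitors. The mutant mice carried Jak2V617F, a change that keeps the cytokine-coupled kinase JAK2 active, and the control mice were wild type. Each of the 4 groups held 4 libraries, and the replicate number was also the batch. Totals ran from 33.4 to 41.5 (in units of 1e6 estimated counts) per library, with 14439 to 16522 genes detected. Levels are CPM (TMM-scaled counts per 1e6) as mean ± SD with n = 4 libraries per group, and log2 fold changes are given ± SE. Adjusted p for genes comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14179 genes, and that for gene lists from camera over 27 lists. The labels do not say that replicates came from separate animals, so each p measures the spread between these samples. Coordinates are those of GRCm38.

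The levels of sorting markers separated the cell types. Cd48, absent from the surface of most stem cells, stood at 2.50 ± 0.769 CPM in control HSC and 185 ± 24.6 CPM in control MPP3. Slamf1, the CD150 marker of HSC, stood at 39.8 ± 13.9 and 1.88 ± 0.759 CPM. Mpo, the myeloperoxidase of early myeloid cells, stood at 9.33 ± 6.29 CPM in control HSC and 5.36 ± 7.69 CPM in mutant HSC, against 2492 ± 856 and 2410.2 ± 579 CPM in the MPP3 groups. Fcgr3 remained at 5.0 ± 3.30 CPM in control MPP3 and 3.38 ± 2.39 CPM in mutant MPP3, and Fcgr2b at 18.7 ± 14 and 23.0 ± 5.92 CPM. Jak2 itself (chromosome 19, 29251828 to 29313080) was expressed at 21.7 ± 5.89 and 25.9 ± 5.23 CPM in control and mutant HSC and at 24.7 ± 5.66 and 24.4 ± 5.51 CPM in control and mutant MPP3. Its log2 fold change in the mutant was 0.25 ± 0.23 in HSC (edgeR adjusted p = 0.604) and -0.02 ± 0.23 in MPP3 (edgeR adjusted p = 0.998). Gene counts do not show the base change, so they do not check the genotype labels. Principal component 1 (32.5% of variance) parted HSC from MPP3. Component 2 (9.68%) parted mutant from control libraries; mutant MPP3 replicate 3 lay nearest the controls, with a score of 10.4 where the lowest control score was 14.5.

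**Figure D1:**
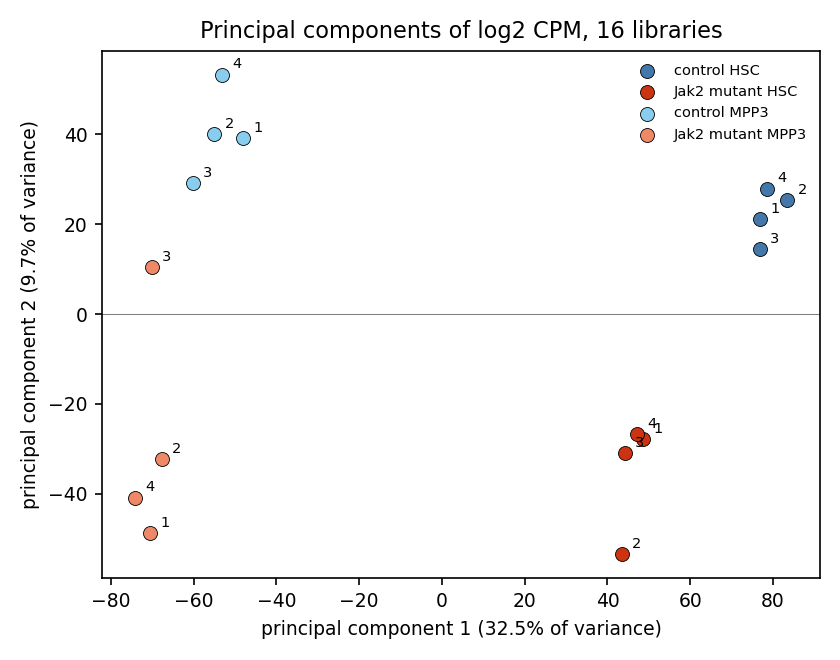
Scores of the 16 libraries on the first principal components of log2 CPM; each point is a library, numbered by replicate, and colours give the groups. Control libraries score from 14.5 to 53.3 on component 2, and 7 of the 8 mutant libraries score below 0.

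The comparison of mutant with control HSC asks what Jak2V617F changes in stem cells, in a series whose title sets the unfolded protein response beside an oncogenic mutation. Mutant HSC held more transcript of the genes that copy DNA and divide the cell, and less of the genes that mark stem cell identity. Of 31 DNA replication genes tested, 30 rose, and 30 rose when adjusted over the list alone, with a median log2 fold change of 0.88. Of 26 mitosis genes, 24 rose (26 when adjusted over the list alone), with a median of 0.86. Of 34 HSC identity genes, 13 fell and none rose (16 fell when adjusted over the list alone), with a median of -0.52.

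Tyms, which makes thymidylate for DNA synthesis (chromosome 5, 30058202 to 30073617), rose from 108 ± 10.7 to 225 ± 26.3 CPM, a log2 fold change of 1.06 ± 0.10 (edgeR adjusted p = 0.000156). The thymidine kinase gene Tk1 rose by 1.08 ± 0.12, the DNA ligase gene Lig1 by 0.96 ± 0.11, and Mcm2, a subunit of the replicative helicase, by 0.85 ± 0.11. Among mitosis genes, the kinase gene Cdk1 rose by 1.03 ± 0.12, its cyclin gene Ccnb1 by 1.15 ± 0.14 and the centromeric histone gene Cenpa by 0.84 ± 0.11. The DNA replication and mitosis lists had camera adjusted p = 2.67e-35 and 6.94e-25, and both had adjusted p = 0.0166 with an estimated correlation. Mllt3, a regulator of stem cell maintenance (chromosome 4, 87769925 to 88033364), fell from 159 ± 16.7 to 73.2 ± 7.0 CPM, a log2 fold change of -1.12 ± 0.13 (edgeR adjusted p = 0.000163). The stem cell transcription factor genes Hlf and Hoxa9 had -0.82 ± 0.11 and -0.73 ± 0.14, and Procr, the EPCR surface marker, had -1.08 ± 0.22. The HSC identity list had camera adjusted p = 2.1e-08, and adjusted p = 0.0342 with an estimated correlation. Slamf1, a member of that list, had -0.08 ± 0.32 (edgeR adjusted p = 0.928). Mitochondrial transcripts made up 1.78 ± 0.268% of counts in control HSC and 1.20 ± 0.209% in mutant HSC.

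Of 32 nuclear genes of oxidative phosphorylation, 17 rose in mutant HSC (27 when adjusted over the list alone), with a median of 0.33. The ATP synthase gene Atp5b rose by 0.47 ± 0.08, Sdhb of complex II by 0.47 ± 0.08 and Cyc1 of complex III by 0.66 ± 0.13. That list had camera adjusted p = 5.05e-15, and adjusted p = 0.0641 with an estimated correlation. Of 26 ribosome biogenesis genes, 4 rose (13 when adjusted over the list alone), among them Rrp12 with 0.88 ± 0.20 (camera adjusted p = 6.94e-07, and adjusted p = 0.339 with an estimated correlation). Among single genes with little overlap in function, Alox5, the 5-lipoxygenase of leukotriene synthesis, rose from 1.98 ± 1.30 to 16.9 ± 5.99 CPM, and Plac8 from 29.3 ± 12.0 to 123 ± 28.5 CPM. Cd48 rose by 1.43 ± 0.21 and reached 6.74 ± 1.71 CPM. Large falls included those of the matrix gene Matn4 (-2.79 ± 0.35), the glycogen phosphorylase gene Pygm (-2.45 ± 0.40) and Trib2 (-2.41 ± 0.44).

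Genes of the unfolded protein response, the programme that cells use against misfolded protein in the endoplasmic reticulum, moved in both directions in mutant HSC. Of 18 sensors and regulators, 3 fell and none rose (3 and none when adjusted over the list alone). Xbp1, the transcription factor of the IRE1 branch (chromosome 11, 5520659 to 5525893), fell from 41.4 ± 6.36 to 19.1 ± 3.94 CPM, a log2 fold change of -1.11 ± 0.21 (edgeR adjusted p = 0.00461). Ern1, which encodes the sensor IRE1 (chromosome 11, 106394650 to 106487852), fell by 1.22 ± 0.33 on the log2 scale (edgeR adjusted p = 0.0343), and Nfe2l1 had -0.48 ± 0.12 (edgeR adjusted p = 0.0229). The list as a whole had camera adjusted p = 0.236. The chaperone gene Hspa5 had 0.07 ± 0.25 (edgeR adjusted p = 0.922) and Atf4 -0.08 ± 0.21 (0.894). Ddit3 had -0.45 ± 0.27 (0.361) and Dnajb9 -0.71 ± 0.27 (0.121). Eif2ak3 had -0.31 ± 0.34 (0.679) and Atf6 -0.01 ± 0.16 (0.981). Of 30 PERK and ATF4 targets, 6 rose and 2 fell (9 and 3 when adjusted over the list alone). The risers included Mthfd2 of mitochondrial folate metabolism (1.25 ± 0.16), Psat1 of serine synthesis (0.86 ± 0.16) and the alanyl-tRNA synthetase gene Aars (0.58 ± 0.11), and the stress pseudokinase gene Trib3 fell (-1.59 ± 0.29). That list had a median of 0.25 but a mean of -0.04. Its camera adjusted p was 0.0240, with adjusted p = 0.402 with an estimated correlation and 0.0864 with batch as a block. Of 22 ATF6 targets and chaperones, 2 rose (2 when adjusted over the list alone): Sdf2l1 with 0.69 ± 0.16 and Calr with 0.50 ± 0.15 (camera adjusted p = 0.0373, and adjusted p = 0.460 with an estimated correlation). Of 33 IRE1 and XBP1s targets, 4 rose and 1 fell (4 and 2 when adjusted over the list alone), among them Rpn1 with 0.45 ± 0.09, Sec24d with 0.84 ± 0.20 and Edem2 with -0.38 ± 0.10 (camera adjusted p = 0.112).

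Several of these calls lay near the threshold and changed when 1 library was left out, which also lowers the power of the test. Ern1 lost its call without mutant replicate 1, 2 or 4 or control replicate 1, 2 or 4 (edgeR adjusted p = 0.0548 to 0.138). Nfe2l1 lost it without any mutant replicate or control replicate 1 or 2 (0.0502 to 0.0939), and Edem2 without any library except control replicate 1 (0.0584 to 0.0897). By the same test Calr lost it without any library except mutant replicate 3 (0.0608 to 0.169) and Sdf2l1 without control replicate 2 (0.0519). The PERK and ATF4 list lost its camera call without mutant or control replicate 2 (0.0901 and 0.114). The ATF6 list lost it without mutant replicate 1 or 4 or control replicate 2, 3 or 4 (0.0517 to 0.162). The IRE1 and XBP1s list gained one without mutant replicate 3 (0.0142) or control replicate 1 (0.00704). Over all alternatives the adjusted p ran from 2.46e-05 to 0.102 for Xbp1, 0.00452 to 0.280 for Ern1, 0.00984 to 0.402 for the PERK and ATF4 list, 0.00261 to 0.460 for the ATF6 list and 0.00704 to 0.580 for the IRE1 and XBP1s list.

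**Figure D2:**
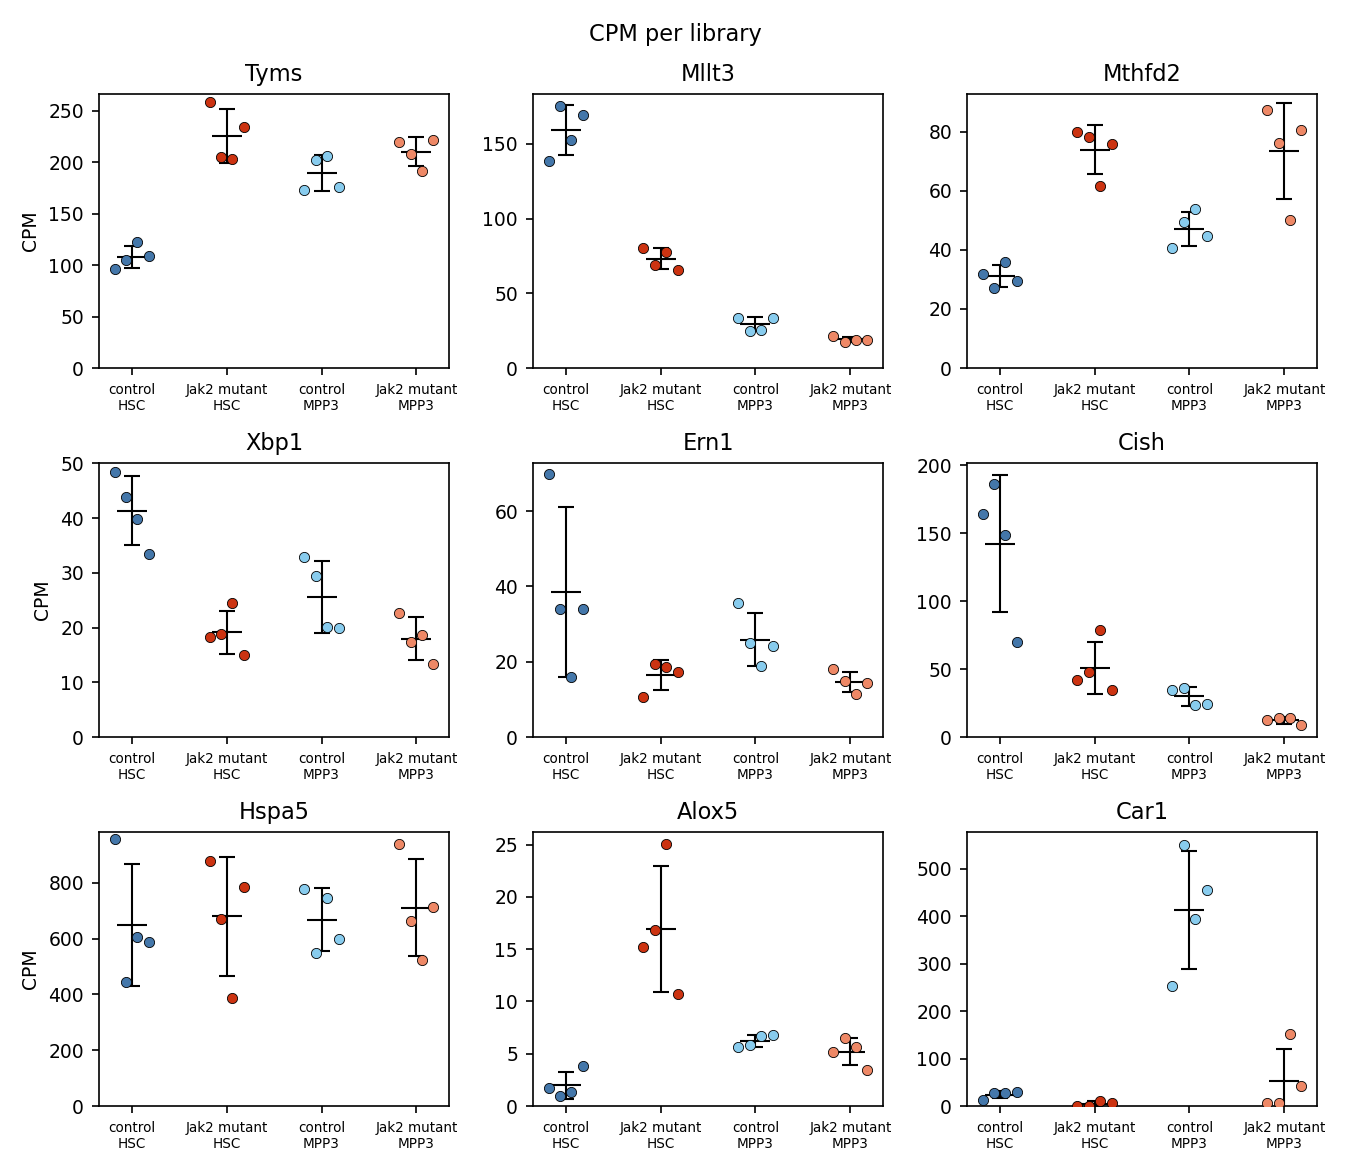
CPM of 9 genes in each library; points are libraries, horizontal marks the group means and bars the SD over 4 libraries. Xbp1 and Mllt3 lie lower and Tyms higher in every mutant HSC library than in every control HSC library, and Hspa5 overlaps between all groups.

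Transcripts induced by JAK-STAT signalling did not rise as a group in mutant HSC. Of 27 targets, 6 fell and none rose (11 fell and 1 rose when adjusted over the list alone). The 6 include Xbp1, which is also among the sensors and regulators above. Cish, a feedback inhibitor induced by STAT5 (chromosome 9, 107296026 to 107302784), fell from 142 ± 50.6 to 50.8 ± 19.5 CPM, a log2 fold change of -1.48 ± 0.29 (edgeR adjusted p = 0.00481). The cytokine receptor gene Il4ra fell (-0.57 ± 0.13, edgeR adjusted p = 0.0122, 0.0523 without mutant replicate 2), and the kinase gene Pim1 had -0.88 ± 0.24 (0.0341). Pim1 lost its call without mutant replicate 2, 3 or 4 or control replicate 1 or 4 (edgeR adjusted p = 0.0734 to 0.118, range over all alternatives 0.00117 to 0.118). Socs2, another STAT5 target, had 0.29 ± 0.40 (edgeR adjusted p = 0.763). The list had camera adjusted p = 0.000737, and adjusted p = 0.251 with an estimated correlation. Among megakaryocyte genes Serpine2 rose by 1.87 ± 0.37, F2rl2 by 1.21 ± 0.31 and Cd9 by 0.45 ± 0.10. F2rl2 lost its call without mutant replicate 1 or 2 or control replicate 2 or 4 (edgeR adjusted p = 0.0568 to 0.0788). In all, 6 of 27 megakaryocyte and platelet genes rose and 1 fell (7 and 2 when adjusted over the list alone; camera adjusted p = 0.153).

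Myeloid and stress lists moved less evenly. Of 30 granulocyte-monocyte progenitor genes, 3 rose and 4 fell (4 and 8 when adjusted over the list alone, camera adjusted p = 0.471). The risers include Calr, given above as an ATF6 target. The granule gene Nkg7 rose by 1.34 ± 0.16 beside Plac8, and the granule protease gene Prtn3 had -0.68 ± 0.17 (edgeR adjusted p = 0.0193, 0.0579 to 0.0726 without control replicate 4 or mutant replicate 1, 2 or 4, range over all alternatives 0.00133 to 0.218). Of 16 neutrophil granule genes, 2 fell (2 when adjusted over the list alone), with medians of -3.39, -3.51, 0.67 and -0.81 in batches 1 to 4 (camera adjusted p = 0.00868, and adjusted p = 0.429 with an estimated correlation). That list had 0.0510 without mutant replicate 1. Padi4, a histone-citrullinating enzyme of neutrophils, was among them, with -1.18 ± 0.18. All 22 immediate early genes had negative fold changes and 2 fell (2 when adjusted over the list alone): Rhob with -1.81 ± 0.42 (edgeR adjusted p = 0.0542 without mutant replicate 4) and Dusp2 with -1.47 ± 0.38 (0.0524 to 0.0924 without control replicate 1 or mutant replicate 1, 3 or 4). That list, which includes transcripts set off by handling of cells, had a median of -1.72 (camera adjusted p = 1.53e-05, and adjusted p = 0.429 with an estimated correlation). Of 25 NF-kB targets, 4 fell (5 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.0181, adjusted p = 0.251 with an estimated correlation, and 0.0501 to 0.0826 without control replicate 2 or 3 or mutant replicate 1 or 4). Of 16 cell cycle brakes, 2 fell (3 when adjusted over the list alone), Foxo3 with -0.69 ± 0.14 and Btg1 with -1.0 ± 0.25, which lost its call by edgeR adjusted p (0.0528 to 0.0787 without control replicate 1 or mutant replicate 2, 3 or 4). The brakes had camera adjusted p = 0.0347, adjusted p = 0.251 with an estimated correlation, and 0.0636 to 0.104 without control replicate 1 or mutant replicate 2 or 4. The other lists had camera adjusted p of 0.471 (interferon response), 0.163 (cytosolic heat shock, 0.0395 without mutant replicate 3), 0.958 (cholesterol synthesis) and 0.519 (glycolysis and hypoxia). Those of other lineages had 0.299 (lymphoid progenitor), 0.304 (erythroid), 0.402 (B cell), 0.601 (T and NK cell), 0.259 (mast cell, basophil and eosinophil), 0.782 (dendritic cell and macrophage) and 0.304 (stroma and endothelium).

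In all, 1035 of 14179 genes changed in mutant HSC, 646 higher and 389 lower, and 221 of them by more than 2-fold. Of the 1035, 1010 went the same way in each of the 4 batches, which calling them on these same libraries favours. DESeq2 called 1801. The count was 605 without mutant replicate 1, 622 without mutant replicate 4, 634 without control replicate 2 and 266 without mutant replicates 1 and 4 together. Mutant replicates 1 and 4 were the most alike pair of replicates (r = 0.971). If they are not independent samples, the 1035 calls rest on fewer than 4 independent mutant samples. Without those 2 mutant libraries Xbp1 (0.102), Cish (0.115) and Procr (0.154) no longer passed by edgeR adjusted p, and Tyms and Mllt3 did.

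The same comparison in MPP3 asks whether the mutant kinase acts alike in the progenitors. Only 9 genes changed there, 2 higher and 7 lower. In the same edgeR fit 1960 of 14179 genes had an unadjusted p under 0.05 in MPP3, against 3080 in HSC, so the 9 do not measure the extent of the effect. Among those that fell were Myo1d (-1.76 ± 0.29), Ctse, a cathepsin gene (-1.54 ± 0.26), Fbxo31 (-1.38 ± 0.24) and Aplp2 (-0.74 ± 0.13). These 4 genes shared an edgeR adjusted p of 0.0469. Each was lower in 4 of 4 batches, which the naming rule of no overlap between groups ensures. Each lost its call in several fits that left out 1 library: Myo1d had 0.0592 to 0.112 without control replicate 2 or 4 or mutant replicate 2 or 4. Ctse had 0.0577 to 0.115 without control replicate 1, 2 or 4 or mutant replicate 1, 2 or 4, Fbxo31 0.0801 to 0.115 without control replicate 1, 2 or 4 or mutant replicate 1, 2 or 4 and Aplp2 0.0519 to 0.115 without control replicate 1, 2, 3 or 4 or mutant replicate 1, 2 or 4.

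A further 4 genes were named after their values were seen. Gbp4, an interferon-induced GTPase gene, stood at 1.89 ± 0.748 CPM in control MPP3 and had no counts in mutant MPP3, at least 23.4-fold lower against a floor of 3 counts per library (edgeR adjusted p = 0.000135). Acsl6 was at least 33.6-fold lower and Spats2 at least 9.83-fold higher against the same floor, which covers counting error only because PCR copies read without molecular identifiers are not independent molecules, and Gm4951 rose by 1.51 ± 0.26 (edgeR adjusted p = 0.0469 for each). With 1 library left out, Acsl6 had 0.0507 to 0.112 without control replicate 1, 2, 3 or 4 or mutant replicate 1, 2 or 4, Spats2 0.0519 to 0.112 without control replicate 1, 2, 3 or 4 or mutant replicate 2 or 4 and Gm4951 0.0747 to 0.115 without control replicate 1, 2, 3 or 4 or mutant replicate 2 or 4, while Gbp4 kept its call in each such fit. Gbp4 lost its call by limma-voom (limma-voom adjusted p = 0.0653) and in the fit on the MPP3 libraries alone (edgeR adjusted p = 0.195). Xbp1 had -0.51 ± 0.21 in MPP3 (edgeR adjusted p = 0.289), Ern1 -0.82 ± 0.33 (0.279) and Hspa5 0.09 ± 0.25 (0.932). By the same test Atf4 had 0.04 ± 0.21 (0.973), Ddit3 -0.45 ± 0.27 (0.506) and Dnajb9 -0.30 ± 0.27 (0.686). Eif2ak3 had 0.28 ± 0.34 (0.801), Atf6 -0.04 ± 0.16 (0.965), Socs2 0.11 ± 0.42 (0.958) and Pim1 -0.42 ± 0.24 (0.463), again by edgeR adjusted p. Cish had -1.28 ± 0.29 (edgeR adjusted p = 0.0886, and 0.0276 with batch as a block, range over all alternatives 0.00164 to 0.234).

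As groups, erythroid and B cell transcripts fell in mutant MPP3, and replication and respiration genes rose, by camera with its preset correlation, and none of these lists passed with an estimated one. Of 31 erythroid genes, 29 had negative fold changes with a median of -1.50, and 5 fell when adjusted over the list alone. By edgeR none passed over all genes, where 13 had an unadjusted p under 0.05 (camera adjusted p = 2.76e-11, and adjusted p = 0.114 with an estimated correlation). The erythroid transcription factor gene Gata1 stood at 39.6 ± 9.84 CPM in control and 17.3 ± 7.94 CPM in mutant MPP3, and the haem-pathway gene Blvrb at 88.8 ± 11.6 and 34.0 ± 19.2 CPM (edgeR adjusted p = 0.119 and 0.0634, the latter 0.00147 without mutant replicate 3 and 0.0264 with batch as a block). Car1, a carbonic anhydrase of red cell precursors and chosen after its values were seen, stood at 253 to 550 CPM in the control libraries and at 6.01, 6.39, 152.5 and 42.4 CPM in mutant replicates 1 to 4. Replicate 3 of the mutant lay nearest the controls, and the list medians by batch ran from -4.09 to -0.37. All 12 B cell genes were lower, with a median of -2.0, and 7 fell when adjusted over the list alone. By edgeR none passed over all genes, where 7 had an unadjusted p under 0.05 (camera adjusted p = 3.78e-09, and adjusted p = 0.114 with an estimated correlation). Jchain stood at 38.4 ± 47.6 CPM in control and 0.187 ± 0.216 CPM in mutant MPP3, and the immunoglobulin gene Igkc at 98.4 ± 132 and 0.926 ± 0.918 CPM (edgeR adjusted p = 0.0841 and 0.143, and 0.0471 and 0.0208 with batch as a block; Jchain 0.0119 without control replicate 1). The lymphoid progenitor list fell with a median of -0.45 and the T and NK cell list with -0.62 (camera adjusted p = 0.000997 and 0.00492, and adjusted p = 0.199 and 0.114 with an estimated correlation). Flt3, which marks the lymphoid-primed side of the multipotent progenitors, stood at 199 ± 33 and 142 ± 32.4 CPM (edgeR adjusted p = 0.187, and 0.0482 without mutant replicate 3).

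The DNA replication list rose with a median of 0.32 and the mitosis list with 0.33, where 9 and 4 genes passed when adjusted over the list alone and none by edgeR over all genes, where 16 and 10 had an unadjusted p under 0.05 (camera adjusted p = 6.63e-12 and 2.61e-08, and adjusted p = 0.114 for both with an estimated correlation). In batches 1 to 4 the list medians were 0.47, 0.21, 0.04 and 0.50 for DNA replication and 0.54, 0.16, 0.02 and 0.59 for mitosis. Pola1 of the replicative polymerase had 0.64 ± 0.14 and the mitotic kinesin gene Kif20a 0.49 ± 0.14 (edgeR adjusted p = 0.0825 and 0.151, the former 0.0460 without mutant replicate 3 and 0.0471 with batch as a block). Oxidative phosphorylation genes rose with a median of 0.23, 14 of 32 when adjusted over the list alone (camera adjusted p = 6.63e-12, and adjusted p = 0.114 with an estimated correlation), and Uqcrq of complex III had 0.54 ± 0.14 (edgeR adjusted p = 0.119, 0.0103 without mutant replicate 3). HSC identity genes fell with a median of -0.21, 7 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00348, and adjusted p = 0.199 with an estimated correlation); Mllt3 had -0.62 ± 0.13 (edgeR adjusted p = 0.0640). Camera also called higher ribosome biogenesis (4.67e-07), glycolysis and hypoxia (0.00117), ATF6 target (0.000426) and PERK and ATF4 target lists (0.0275), and lower cell cycle brake (0.00730), immediate early (0.0184), neutrophil granule (0.0218) and NF-kB lists (0.0218). The neutrophil list had medians of -3.54, -4.11, 3.59 and -3.46 in batches 1 to 4. In the order named the adjusted p of these 8 lists was 0.204, 0.114, 0.199, 0.328, 0.114, 0.577, 0.490 and 0.199 with an estimated correlation. The PERK and ATF4 list had a median of 0.19 but a mean of -0.11, and its adjusted p was 0.0814 with batch as a block. The JAK-STAT target list had camera adjusted p = 0.0505, which became 0.0105 with batch as a block, with a median of -0.25 (range over all alternatives 0.00549 to 0.661).

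Leaving out 1 library moved several of these lists across the threshold by camera adjusted p. The PERK and ATF4 list had 0.0816 to 0.117 without control replicate 2 or 4 or mutant replicate 1 or 2 and the immediate early list 0.0804 to 0.661 without control replicate 1 or mutant replicate 3 or 4. The neutrophil granule list had 0.0619 to 0.183 without control replicate 1 or 2 or mutant replicate 1, 2 or 4, the NF-kB list 0.0823 to 0.0959 without control replicate 1 or mutant replicate 1 or 4 and the brakes 0.0540 without control replicate 1. The JAK-STAT target list had 0.00549 to 0.0449 without control replicate 2, 3 or 4 or mutant replicate 1, the IRE1 and XBP1s list 0.0393 to 0.0460 without control replicate 3 or mutant replicate 3 (all libraries 0.0567) and the interferon list 0.0353 without control replicate 4 (all libraries 0.174). When adjusted over the list alone, 5 ribosome biogenesis, 3 glycolysis and hypoxia and 5 PERK and ATF4 genes were higher, and 3 brakes, 1 neutrophil granule and 1 NF-kB gene lower.

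The small count of single genes moved with the fit. With batch as a block 82 genes changed, 25 higher and 57 lower, and all 9 were among them; DESeq2 called 499, and edgeR on the 8 MPP3 libraries alone called 0, where 1543 had an unadjusted p under 0.05. Without mutant replicate 3 the count was 209, and it was 1, 1 and 2 without control replicate 2, control replicate 4 and mutant replicate 4.

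**Figure D3:**
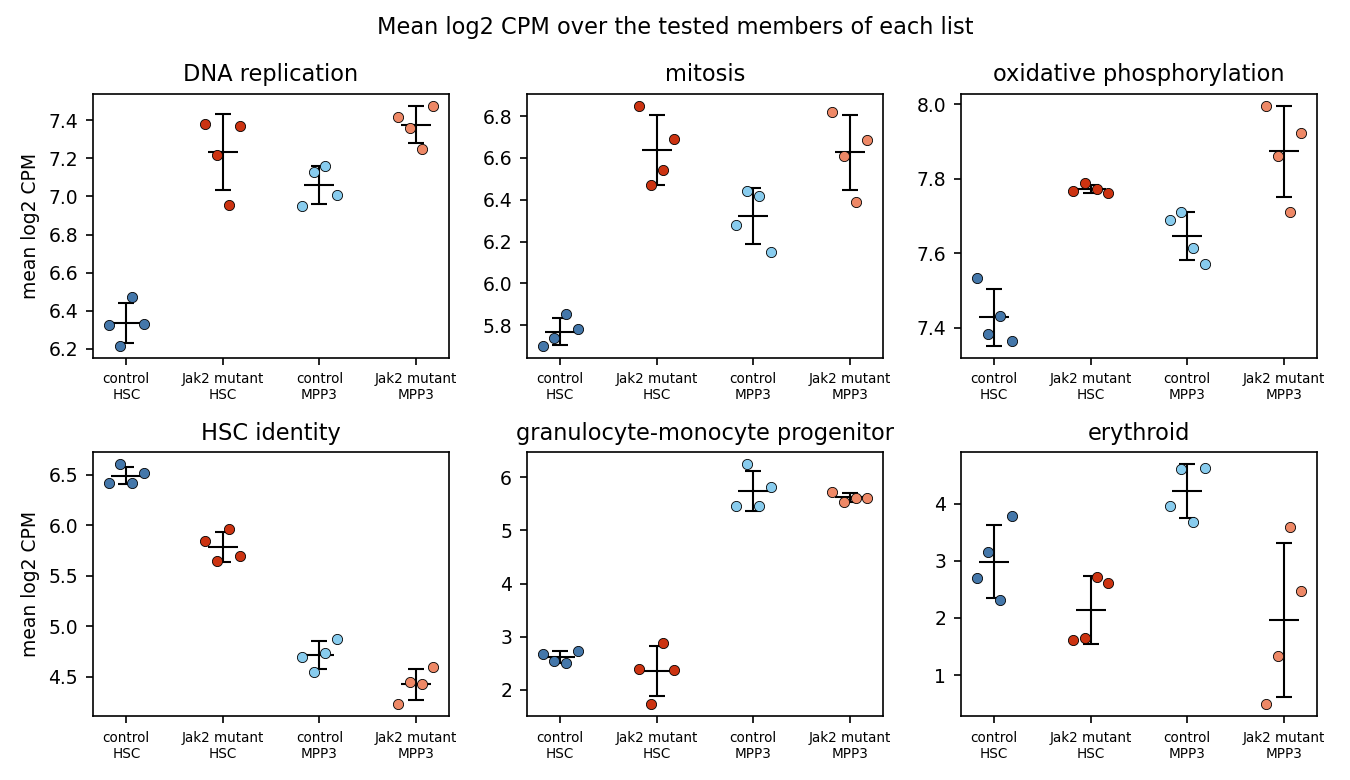
Mean log2 CPM over the tested members of 6 gene lists in each library; points are libraries, horizontal marks the group means and bars the SD over 4 libraries. DNA replication and mitosis scores of every mutant HSC library exceed those of every control HSC library, and the erythroid score of mutant MPP3 replicate 3 lies nearest the control MPP3 libraries.

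The comparison of MPP3 with HSC describes how the progenitors differ from stem cells of the same genotype. In control mice, MPP3 held more myeloid and lymphoid transcripts and fewer stem cell and platelet transcripts. Of 30 granulocyte-monocyte progenitor genes, 24 rose (26 rose and 1 fell when adjusted over the list alone), with a median of 2.95. Of 34 HSC identity genes 26 fell (29 when adjusted over the list alone), with a median of -1.41, and of 27 megakaryocyte and platelet genes 19 fell and 1 rose (20 and 2 when adjusted over the list alone), with a median of -1.86. In all 1926 genes changed, 946 higher and 980 lower.

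Mpo rose by 8.06 ± 1.32 on the log2 scale (edgeR adjusted p = 0.00130), the granule protease gene Ctsg by 8.49 ± 0.76 and Plac8 by 4.24 ± 0.24. Cd48 rose by 6.21 ± 0.24 (edgeR adjusted p = 4.39e-11). Vwf, which encodes the platelet adhesion factor, had -4.94 ± 0.35, the platelet chemokine gene Pf4 -4.88 ± 0.34 and Slamf1 -4.41 ± 0.37. Cavin2 went from 92.8 ± 19.0 to 0.00663 ± 0.0133 CPM, and Matn4, with no counts in control MPP3, was at least 195-fold lower. These lists had camera adjusted p = 4.25e-21, 3.36e-23 and 1.06e-16, and adjusted p = 0.000816, 0.000626 and 0.000626 with an estimated correlation. Of 18 lymphoid progenitor genes, 12 rose and 2 fell (14 and 2 when adjusted over the list alone; camera adjusted p = 1.32e-11, and adjusted p = 0.0123 with an estimated correlation). The tyrosine kinase receptor gene Flt3 rose by 2.89 ± 0.17, the chromatin organiser gene Satb1 by 3.63 ± 0.21 and Dntt, which adds bases at receptor joints, by 8.11 ± 0.99. Of 12 B cell genes 8 rose (10 when adjusted over the list alone), and Vpreb1 of the pre-B receptor was at least 184-fold higher (camera adjusted p = 1.3e-11, and adjusted p = 0.0274 with an estimated correlation). Of 14 T and NK cell genes 3 rose (5 when adjusted over the list alone), and the T cell receptor gene Trbc1 was at least 257-fold higher (camera adjusted p = 0.000557, and adjusted p = 0.0188 with an estimated correlation). Of 10 mast cell, basophil and eosinophil genes 5 rose (6 when adjusted over the list alone), among them the mast cell protease gene Cpa3 with 3.57 ± 0.39 (camera adjusted p = 5.7e-06, and adjusted p = 0.00744 with an estimated correlation).

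Control MPP3 also held more replication transcripts than control HSC. Of 31 DNA replication genes 26 rose (29 when adjusted over the list alone), with a median of 0.71 (camera adjusted p = 3.88e-19, and adjusted p = 0.0345 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 1.26 ± 0.18, and Cdc6, a licensing factor gene, by 1.22 ± 0.17. Of 26 mitosis genes 14 rose (23 when adjusted over the list alone; camera adjusted p = 5e-10, and adjusted p = 0.0627 with an estimated correlation). Among unfolded protein response genes, the stress gene Nupr1 had -4.55 ± 0.40 and Trib3 -2.56 ± 0.30, while Xbp1 had -0.69 ± 0.21 (edgeR adjusted p = 0.0373, 0.0647 to 0.111 without HSC replicate 1, 2 or 3 or MPP3 replicate 3 or 4, range over all alternatives 0.00876 to 0.111). The ATF6 list had camera adjusted p = 0.0656 and the erythroid list 0.0656, which became 0.0450 and 0.0315 with batch as a block. JAK-STAT targets fell (7 of 27 lower and 1 higher, the same when adjusted over the list alone), among them Socs2 with -3.38 ± 0.45 and Cish with -2.25 ± 0.30 (camera adjusted p = 0.0132, and adjusted p = 0.340 with an estimated correlation). By camera the oxidative phosphorylation, ribosome biogenesis, heat shock and neutrophil granule lists were higher and the interferon response and immediate early lists lower. Their adjusted p was 3.17e-05, 0.000678, 0.0121, 0.0182, 0.0271 and 0.0132, and adjusted p = 0.294, 0.438, 0.381, 0.492, 0.438 and 0.601 with an estimated correlation. With 1 library left out the camera adjusted p was 0.0569 to 0.0814 without HSC replicate 1 or MPP3 replicate 2 for JAK-STAT targets and 0.133 to 0.16 without HSC replicate 4 or MPP3 replicate 2 for the interferon list. It was 0.0838 to 0.219 without HSC replicate 1 or MPP3 replicate 3 or 4 for the immediate early list and 0.0781 without MPP3 replicate 2 for the neutrophil list. It crossed the other way for the ATF6 list (0.0231 without HSC replicate 1), the IRE1 and XBP1s list (0.0206 without HSC replicate 1) and the erythroid list (0.0214 to 0.0464 without HSC replicate 4 or MPP3 replicate 1 or 3).

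In mutant mice, MPP3 differed from HSC in myeloid, stem cell and platelet genes, and no single replication gene was called. Of 30 granulocyte-monocyte progenitor genes 27 rose (28 rose and 1 fell when adjusted over the list alone), with a median of 2.64 (camera adjusted p = 1.4e-31, and adjusted p = 0.000165 with an estimated correlation). HSC identity genes fell (22 of 34, 25 when adjusted over the list alone) and so did megakaryocyte and platelet genes (19 of 27, 21 when adjusted over the list alone), with camera adjusted p = 3.12e-18 and 1.03e-26, and adjusted p = 0.00142 and 5.95e-05 with an estimated correlation. The glycolytic gene Hk3 rose by 2.41 ± 0.22 and Mpo by 8.81 ± 1.37, Ctsg went from 0.0133 ± 0.0266 to 81.9 ± 33.4 CPM, and Pf4 had -5.93 ± 0.35. By edgeR no DNA replication or mitosis gene changed, also when adjusted over the list alone, and 9 and 0 had an unadjusted p under 0.05; Tyms stood at 225 ± 26.3 CPM in mutant HSC and 210.3 ± 13.8 CPM in mutant MPP3. The DNA replication list had a median of 0.18 (camera adjusted p = 0.0123, and adjusted p = 0.544 with an estimated correlation) and the mitosis list 0.01 (camera adjusted p = 0.860). The lymphoid progenitor and mast cell lists rose (camera adjusted p = 4.87e-12 and 1.82e-05, and adjusted p = 0.0102 and 0.00988 with an estimated correlation). The B cell and T and NK cell lists were higher too (camera adjusted p = 2.83e-08 and 0.00695, and adjusted p = 0.0748 and 0.0605 with an estimated correlation). A further 8 lists passed camera alone (neutrophil granule, ribosome biogenesis, ATF6 target, oxidative phosphorylation, glycolysis and heat shock lists higher, interferon response and stroma lists lower), with adjusted p from 0.125 to 0.544 with an estimated correlation.

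In mutant mice 1186 genes differed between the cell types, 523 higher and 663 lower in MPP3. Of the genes called in either genotype, 353 were higher in both and 468 lower in both, where independent lists would share 34.9 and 45.8, and 1 went opposite ways. The count in mutants was 776 without mutant HSC replicates 1 and 4 together, and 8 lists passed without mutant HSC replicate 3 and 10 without mutant MPP3 replicate 1, against 16 with all libraries. By camera adjusted p, the DNA replication list had 0.0797 to 0.290 without HSC replicate 3 or MPP3 replicate 4, the ATF6 list 0.0526 to 0.0753 without HSC replicate 3 or MPP3 replicate 1, and ribosome biogenesis 0.106 without HSC replicate 3. Oxidative phosphorylation had 0.0502 to 0.166 without HSC replicate 3 or 4 or MPP3 replicate 1 or 4, and glycolysis 0.0502 to 0.0797 without HSC replicate 3 or MPP3 replicate 1 or 4. Heat shock genes had 0.0556 to 0.149 without HSC replicate 3 or 4 or MPP3 replicate 1, 2 or 4, and interferon response genes 0.0753 to 0.0982 without HSC replicate 3 or 4 or MPP3 replicate 1 or 2. The remaining ones were stroma 0.0540 to 0.0797 without HSC replicate 2, 3 or 4 or MPP3 replicate 1, 2 or 4 and neutrophil granule genes 0.0562 without MPP3 replicate 3.

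The difference between the mutant effect in MPP3 and that in HSC was tested directly. As lists, replication and mitosis genes had smaller fold changes in MPP3 than in HSC by camera with its preset correlation, but not with an estimated one. All 31 DNA replication genes had a smaller effect in MPP3, with a median difference of -0.53 on the log2 scale, and 23 differed when adjusted over the list alone against 1 over all genes (camera adjusted p = 1.37e-22, and adjusted p = 0.0779 with an estimated correlation). Tyms, the 1 gene, had a difference of -0.90 ± 0.14 (edgeR adjusted p = 0.0327, 0.110 with batch as a block, and 0.0537 to 0.101 without any 1 library except control HSC replicate 3, mutant HSC replicate 3 or mutant MPP3 replicate 4, range over all alternatives 1.55e-06 to 0.245). All 26 mitosis genes had a smaller effect too, with a median of -0.61, and 12 differed when adjusted over the list alone (camera adjusted p = 5.7e-15, and adjusted p = 0.0779 with an estimated correlation). The membrane protein gene Ifitm1 went from 686 ± 91.9 to 308 ± 55.8 CPM in HSC and from 332 ± 33.4 to 414 ± 89.3 CPM in MPP3, a difference of 1.48 ± 0.21 (edgeR adjusted p = 0.0189, 0.0688 with batch as a block, and 0.0564 to 0.0829 without control HSC replicate 2 or mutant HSC replicate 1 or 2 or control MPP3 replicate 2 or 3). Alox5 and Plac8 differed by -3.36 ± 0.54 and -1.78 ± 0.30, both with a larger rise in HSC (edgeR adjusted p = 0.0327 and 0.0441, and 0.128 and 0.151 with batch as a block). Alox5 had 0.0512 to 0.101 without any 1 library except control HSC replicate 4 or mutant HSC replicate 4, and Plac8 0.0607 to 0.117 without any 1 library except control HSC replicate 4. Xbp1 differed by 0.60 ± 0.30 (edgeR adjusted p = 0.741), Ern1 by 0.40 ± 0.47 (0.984) and Cish by 0.20 ± 0.40 (1.000), so a difference between the cell types was not shown for them. Over all genes, 6 differed, including Gbp4 and, chosen after its values were seen, Spats2 (0.185 with batch as a block), which had 0.0608 to 0.101 without any 1 library except mutant MPP3 replicate 3. With batch as a block 1 remained, Gbp4 (edgeR adjusted p = 0.0369). With a block per genotype and batch Gbp4 had 0.142, and the 1 that remained was Tyms; Gbp4 also lost its call by limma-voom (0.321) and without mutant HSC replicates 1 and 4 (0.0623). The count was 0 without mutant HSC replicates 1 and 4, where 891 genes had an unadjusted p under 0.05 in edgeR; DESeq2 on all libraries called 94. Leaving out any 1 of the 16 libraries gave counts from 1 to 5.

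A further 7 lists differed by camera with its preset correlation. HSC identity (0.38), JAK-STAT target (0.21) and immediate early lists (0.31) had positive median differences. Megakaryocyte and platelet (-0.43), erythroid (-0.71), B cell (-1.71) and oxidative phosphorylation lists (-0.12) had negative ones. In that order the camera adjusted p was 0.000102, 0.0396, 0.0155, 0.0155, 5.61e-06, 3.12e-05 and 0.0155, and adjusted p = 0.216, 0.501, 0.848, 0.254, 0.354, 0.254 and 0.734 with an estimated correlation. By camera adjusted p, JAK-STAT targets had 0.0559 to 0.204 without control HSC replicate 1 or mutant HSC replicate 4 or control MPP3 replicate 2, 3 or 4 or mutant MPP3 replicate 1 or 3, the immediate early list 0.0682 to 0.386 without control HSC replicate 1 or mutant HSC replicate 3 or 4 or control MPP3 replicate 3 or 4 or mutant MPP3 replicate 1, the megakaryocyte list 0.0578 to 0.100 without control HSC replicate 2 or 3 or mutant HSC replicate 2 or control MPP3 replicate 4 or mutant MPP3 replicate 1 or 2 and oxidative phosphorylation 0.0696 to 0.258 without control HSC replicate 4 or mutant MPP3 replicate 3. The lists of unfolded protein response sensors, PERK and ATF4, IRE1 and XBP1s and ATF6 targets had camera adjusted p = 0.273, 0.619, 0.860 and 0.562.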

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

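The tests of other splits of the samples and of the spread among MPP3 libraries were chosen before their results were seen, and the other tests in this part after. In groups of 4 libraries, 462 values of named genes, lists and library measures were tested for 1 library standing apart, and 18 (3.90%) did, where chance gives about 1 in 20. Genes are given in log2 CPM. Control HSC replicate 1 had Car1 at 3.63 (lowest, others 4.80 to 4.84), Dnajb9 at 5.6 (highest, others 4.41 to 4.58) and Uqcrq at 6.63 (highest, others 6.27 to 6.32). Control HSC replicate 3 had Dntt at 0.32 (highest, others all -4.24) and Mpo at -4.24 (lowest, others 3.50 to 3.76). Control MPP3 replicate 1 had Dnajb9 at 4.61 (highest, others 3.84 to 3.97) and Rhob at 4.34 (highest, others 2.78 to 2.96). Mutant HSC replicate 2 had Slamf1 at 5.05 (lowest, others 5.27 to 5.31). Mutant HSC replicate 3 had Nfe2l1 at 5.78 (lowest, others 5.94 to 5.96), Procr at 5.99 (highest, others 5.15 to 5.28) and Rrp12 at 6.32 (lowest, others 6.76 to 6.84). Mutant MPP3 replicate 3 had Ctse at 5.76 (highest, others 4.58 to 4.74), Flt3 at 7.57 (highest, others 6.95 to 7.02) and Trib3 at 3.65 (highest, others 2.04 to 2.21). Of the other measures, the haemoglobin share of counts (percent) was 0.0214 in mutant MPP3 replicate 4 (highest, others 0.00783 to 0.00901), the mitochondrial share of counts (percent) was 1.23 in mutant MPP3 replicate 4 (lowest, others 1.40 to 1.41), the mean log2 CPM of JAK-STAT targets was 5.59 in control MPP3 replicate 1 (highest, others 4.94 to 5.02) and the mean log2 CPM of PERK and ATF4 targets was 5.08 in mutant HSC replicate 3 (lowest, others 5.29 to 5.33). No cause was tested for these values.

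The mutant effect differed between the cell types by a test of the difference itself for 6 genes and, by camera with its preset correlation, 9 lists, none of which passed with an estimated one. On the log2 scale, MPP3 minus HSC, the genes were Gbp4 -7.84, Ifitm1 1.48, Tyms -0.90, Alox5 -3.36, Spats2 9.54 and Plac8 -1.78, where Gbp4 had no counts in mutant MPP3 and Spats2 none in control MPP3, so their fitted values are no bounds. The list medians were JAK-STAT targets 0.21, HSC identity 0.38, megakaryocyte and platelet -0.43, erythroid -0.71, B cell -1.71, mitosis -0.61, DNA replication -0.53, immediate early 0.31 and oxidative phosphorylation -0.12. In the split test, 5 of 100 splits of the samples, the real one included, gave as many genes as the real 6, with a highest other of 1093. The 4 splits with more genes kept the HSC genotypes whole, as labelled or exchanged, against mixed or mostly opposed MPP3 labels, a structure of the samples that turns the mutant effect itself into a difference. They are no measure of chance, so the test decides nothing for that count; the other 95 splits called at most 1. In each of the 4 pairwise comparisons 1 of 35 splits, the real one, gave as many genes, which excludes chance only if libraries could be exchanged across batches: 1035 in HSC (highest other 31), 9 in MPP3 (4), 1926 between cell types in controls (1) and 1186 in mutants (6). The split with 6 set batches 1 and 4 against batches 2 and 3, which differ in Y-linked transcripts, and the count with batch as a block was 1360. Within batches only 8 splits part every pair, too few for a share under 0.05, and the highest counts of the 7 others were 0, 0, 1 and 0.

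The rise of DNA replication and mitosis genes in mutant HSC may come from a change in the sorted cells. If MPP3-type cells within the sort were the whole source, the 54 called genes would need a median share of 88.2% of such cells (quartiles 73.6% to 111%). The 13 abundant MPP3 transcripts (at least 20 CPM there and over 20-fold above control HSC) show a median share of 0.848% (libraries -0.183% to 1.43%, largest single transcript 6.10%), which argues against it. The minimum of 20 CPM was lowered after a first run with a higher one, which led to the same verdict. Megakaryocyte-type progenitors remain open, since that list had a median log2 fold change of 0.23 with members moving both ways (camera adjusted p = 0.153, and 0.429 with an estimated correlation), and so does more cycling of HSC themselves, which was not tested apart from the transcripts.

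Fewer genes changed in mutant MPP3 than in mutant HSC. Larger independent noise among MPP3 libraries is not the whole cause by the covariance of mutant effects between separate batches, which such noise does not change on average. That covariance was at most 0.173 in MPP3 (0.168 to 0.173) and at least 0.223 in HSC (0.223 to 0.254) over 3 splits of the batches and 14179 genes. The spread was larger too, with noise of 0.667 to 0.677 against 0.518 to 0.581 and a common coefficient of variation of 0.478 against 0.406, so part of the difference may come from it. Mutant MPP3 replicate 3, near the controls, is not the whole cause, since 209 genes were called without it, and the lowest count in HSC with 1 library left out was 605. That library was in each split of the batches, where it can lower the covariance in MPP3, and the covariance was not computed without it. Noise and that library together were not tested as the cause. A smaller effect of the mutation in MPP3 stays a hypothesis.

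Erythroid and B cell lists were lower in mutant MPP3 by camera with its preset correlation, but in the main edgeR fit no member passed over all genes (some did in other fits, as with batch as a block or by DESeq2), and each list had camera adjusted p = 0.114 with an estimated correlation. Fewer stray cells of every other type would lower all their transcripts. The 4 T and NK cell genes used were lower in every batch (median -1.07, batches -1.73 to -0.91). The stroma, megakaryocyte and dendritic cell lists had under 3 usable genes; over all tested members their batch medians were -1.67 to -0.21, -0.24 to 0.13 and -0.01 to 0.07. The 4 mast cell and basophil genes used (Cpa3, Mcpt8, Hdc, Cyp11a1) had a median of 0.26 (batches -0.09 to 0.84), where 27 erythroid genes had batch medians from -4.09 to -0.43. MPP3 of this gate may themselves make mast cell transcripts, so that list alone excludes nothing, and fewer stray cells stay open. The test was narrowed after a first run to members above control HSC, and after a second made to need 2 lists that did not fall. The 11 neutrophil genes used had batch medians of -4.31, -4.05, 3.98 and -3.89. The fall of the B cell list does not rest on Igkc and Jchain alone. Without them, 10 B cell genes had a median of -1.81 (batches -3.48 to -0.49, unadjusted camera p = 2.13e-08 by limma, and 0.0140 with an estimated correlation). Antibody-secreting cells may express some of these 10 genes as well. The test therefore does not exclude such cells in some control libraries as a source. Fewer erythroid-primed and lymphoid-primed cells within the gate, or lower transcripts in each cell, stay open too and cannot be separated in sorted bulk RNA.

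Rows named as single transcripts, left out of the tests, held 0.744% of counts on average over the 16 libraries, a signal outside the gene rows.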

How the results depend on the processing

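The fits with transcript rows counted, with a block per genotype, and without mutant HSC replicates 1 and 4 together were chosen after the data were seen. No result changed direction with a call under any alternative run. Mutant against control in HSC called 1035 genes, 1801 by DESeq2, 605 to 1412 with 1 library left out (605, 622 and 634 without mutant replicate 1, mutant replicate 4 and control replicate 2) and 266 without mutant replicates 1 and 4; it called 12 lists, 3 with an estimated correlation and 9 to 14 with 1 library left out. In MPP3 edgeR called 9 genes: 499 by DESeq2, 82 with batch as a block, 16 with effective-length offsets, 1 with no filter, 1 with transcript rows counted, 0 on the groups compared only (1543 at an unadjusted p under 0.05), and 1 to 209 with 1 library left out (209 and 2 without mutant replicate 3 and 4, 1 without control replicate 2 or 4). Camera called 16 lists there, 0 with an estimated correlation (8 at an unadjusted p under 0.05) and 12 to 18 with 1 library left out. These counts of lists are all those called in each fit, newly called ones included. For MPP3 against HSC, 1926 genes in controls were 1396 to 1608 with 1 library left out, and camera called 16 lists, 8 with an estimated correlation. In mutants 1186 genes were 917 to 1133, and 776 without mutant HSC replicates 1 and 4; fry called 10 lists and camera 16, 5 with an estimated correlation and 8 to 17 with 1 library left out (8 without HSC replicate 3, 10 without MPP3 replicate 1). The difference of effects called 6 genes: 94 by DESeq2, 1 with batch as a block (Gbp4), 1 with a block per genotype (Tyms), 0 without mutant HSC replicates 1 and 4 (891 at an unadjusted p under 0.05 in edgeR), and 1 to 5 with 1 library left out. Camera called 9 lists, 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 2. Fewer libraries lower the power of a test; for the other alternatives the cause was not tested. Batch as a block changed no call of a gene or list given with a value in the comparisons other than those printed there. With RLE factors the counts of genes were 1047, 9, 1913, 1171 and 6. At the spread pooled over all 16 libraries, 1.5-fold changes were mostly missed: 0% to 25.4% of them were recovered in simulated data.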

Other observations

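The tests in this part were chosen after results were seen. Mutant effects in HSC and MPP3 were related across genes, which are not independent replicates: r was 0.311 over all batches, and 0.131 to 0.183 when the effects came from separate batches. Effects from separate batches rest on fewer libraries, and the added noise lowers r. The covariance, which independent noise does not change on average, was 0.159 over all batches and 0.0925 to 0.173 from separate ones. All separate values except the highest lay below 0.159, so deviations shared within batches may add to the relation over all batches. Of the genes called in HSC, 963 (93.0%) had the same sign in MPP3, and 2 were called in both. That share used all batches for both effects, so deviations shared within batches can raise it. It was not computed over all genes or from separate batches. Over 57 replication and mitosis genes, the median log2 fold change was 0.86 in HSC and 0.32 in MPP3.

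Of genes called both in mutant against control HSC and in control MPP3 against control HSC, 334 were higher in both and 161 lower in both, where independent lists would share 43.1 and 26.9, and 21 went opposite ways. Both comparisons use the control HSC libraries, which alone gives a relation. The observed r was 0.456. In 20 simulations with no true change in either comparison, r was 0.502 on average. True changes in either comparison alter r, so the simulated r is no baseline for the observed r and decides nothing. The covariance was 0.386 against 0.151 simulated. With the control HSC split between the comparisons r was 0.196 to 0.244 and the covariance 0.203 to 0.243 over 6 splits.

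In the 5 Mb on each side of Jak2 on chromosome 19, 3 of 45 tested genes were called in HSC (6.67%), against 7.30% elsewhere. The Y-linked transcript Ddx3y was at 0 CPM in batches 1 and 4, and at 33.4 to 66.8 CPM in batch 2 and 34.6 to 53.8 CPM in batch 3, in all 4 groups. Eif2s3y was at 0 to 0.637 CPM in batch 1, 0 in batch 4, 37.1 to 49.4 CPM in batch 2 and 27.1 to 37.6 CPM in batch 3. Uty was at 0.0277 to 0.145 CPM in batch 1 and 0.0730 to 0.221 CPM in batch 4. It stood at 13.8 to 20.1 CPM in batch 2 and 10.5 to 26.0 CPM in batch 3. Kdm5d, also Y-linked, was lower but not absent in batches 1 and 4 (7.64 to 9.99 and 8.00 to 13.6 CPM). It stood at 17.1 to 25.5 CPM in batch 2 and 14.9 to 24.3 CPM in batch 3. Each batch held the same pattern in every group, so these transcripts do not separate the groups compared. The main model had no batch term, so such differences between batches are part of its spread.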
